A study of Homo sapiens with 4 samples.

How the data were processed

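Total RNA was measured by sequencing in 4 libraries from primary human macrophages: M1 cells, M2 cells and the EVs released by each, with 1 library per group. Per the labels, RNA was extracted with Trizol, ribosomal RNA was removed with Ribo-Zero gold and libraries were made with the NEB Ultra II kit. Per the submitters' processing notes, reads were aligned with STAR 2.6.1 to build hg38. How reads were counted per gene, whether by strand, and how they were scaled is not stated in the sources used here. The labels give peripheral blood as the tissue of all 4 samples but name another origin in a second field for the cell samples, so the origin of the cells is left open.

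The deposited values are on the log2 scale, as log2 CPM (read counts scaled to a library of 1000000), for each gene and library. They equal the log2 of the read count plus 0.5 over a library size, times 1000000. Whole reads were recovered from them for 100% of the 27778 features in each library within a tolerance of 1e-06, with the lowest value taken as 0 reads. The library size implied by the values was 1.08, 0.968, 0.931 and 1.05 times the summed reads in M1 cells, M1 EVs, M2 cells and M2 EVs, so a scaling factor had been applied by the authors. It was removed here by going back to the reads. Symbols were matched to 27745 features, and gene classes, exonic lengths and positions came from GENCODE release 29 and the RefSeq annotation of GRCh38.p14. One read corresponds to 5.76 CPM in M1 EVs and 5.45 CPM in M2 EVs, and to 0.174 and 0.130 CPM in M1 and M2 cells. A count of 0 allows up to 3 reads, or 17.3, 16.3, 0.522 and 0.391 CPM in the same order.

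Ratios were computed between pairs of libraries as log2 of CPM over the library total, with 0.5 read added to each library, for genes with at least 50 reads in at least 1 of the 2 libraries. The plan foresaw this for counts and, for CPM, the deposited values with a pseudocount of 1 CPM and a floor of 5 CPM. The count form was used because whole reads were recovered and because 5 CPM is less than 1 read in the EV libraries. The other form is among the alternatives, where it was chosen after seeing the data. Each ratio has an exact conditional binomial (Clopper-Pearson) 95% interval, and genes were counted as higher or lower at a ratio of at least 2-fold. With 1 library per group no comparison could be tested against a spread between replicates, and no p-value was computed. A fit over all 4 libraries that takes M1 and M2 as replicates of EVs against cells was not run. The 4 comparisons were M1 with M2 cells, M1 with M2 EVs, M1 EVs with M1 cells and M2 EVs with M2 cells, and 2 correlations across genes were computed.

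For each of 38 gene lists (macrophage states and functions, metabolism, translation, noncoding RNAs, vesicle proteins and markers of other cell types), the median log2 ratio of the members past the floor was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list was said to stand apart at a percentile of at most 2.5 or at least 97.5 with at least 5 members past the floor. The percentile describes these libraries and is not a p-value. The lists, the size rule, the floor, the first 6 alternatives below and the rule for named genes were set before the data were examined. That rule took, among protein-coding genes with at least 200 reads in at least 1 of the 2 libraries, the 6 highest and the 6 lowest ratios; up to 4 members past the floor with the largest ratios, in either direction, of each list that stood apart and of the M1 and M2 polarization lists; and the 5 features with most reads in each library. It left out Y-linked genes, XIST, antigen receptor segments and genes that often vary in copy number between people.

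The alternatives set beforehand were median-of-ratios and TMM scaling (own code, trims of 30% of ratios and 5% of levels), a floor of 200 reads, no floor, a prior of 5 reads, and nuclear protein-coding genes alone. Added after seeing the data were the deposited log2 CPM, EV libraries with an even background subtracted, and counts restricted to genes whose interval lay wholly beyond 2-fold. The background was the density of EV reads per kilobase of exon in coding genes with 0 reads in both cell libraries. Exonic length was first taken over all annotated exons and then, after the first values were seen, over transcripts paired with RefSeq. Both forms are given where they matter. The procedure was tested on simulated data with 20 draws per comparison. Intervals covered the simulated ratio in 95.5% (cells), 95.9% (EVs), 97.0% (M1 EVs with M1 cells) and 97.1% (M2 EVs with M2 cells) of genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.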

Results

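The data held 4 RNA sequencing libraries from primary human macrophages and from the extracellular vesicles (EVs) that they released, with 1 library in each of 4 groups: M1 cells, M1 EVs, M2 cells and M2 EVs. M1 and M2 are the labels' names for the classically activated, inflammatory macrophage state and for the alternatively activated, repair-associated state. Per the submitters' description, the macrophages shared medium, across a transwell membrane, with mesenchymal stromal cells (MSCs) activated by lipopolysaccharide, and RNA was taken after the MSCs were removed and the medium was replaced by one with 2% exosome-free serum. The libraries held 5753152 reads (M1 cells), 7666069 reads (M2 cells), 173754 reads (M1 EVs) and 183644 reads (M2 EVs) in 27778 features. No group had a replicate, so no difference could be set against a spread between replicates, and higher and lower describe these 4 libraries. The intervals are 95% intervals for counting error alone, since reads amplified by PCR without molecular identifiers are not independent molecules. Macrophages that had not been cultured with MSCs were not analysed here, so no value measures an effect of the MSCs.

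The cell libraries consisted mainly of messenger RNA, and the EV libraries held large amounts of small structural RNA. Protein-coding genes of the nuclear genome took 94.96% (Clopper-Pearson 95% interval 94.94 to 94.98) of the reads of M1 cells and 94.04% (94.02 to 94.06) of those of M2 cells, against 68.9% (68.7 to 69.1) in M1 EVs and 74.9% (74.7 to 75.1) in M2 EVs. The 7SL RNA of the signal recognition particle, which directs secreted proteins to the endoplasmic reticulum, took 13.7% (13.5 to 13.8) of the reads of M1 EVs and 8.89% (8.76 to 9.02) of those of M2 EVs, against 0.0352% (0.0337 to 0.0368) and 0.0518% (0.0502 to 0.0534) in the respective cells. The ribosomal RNAs of the mitochondrion took 6.82% (6.70 to 6.94) and 5.38% (5.28 to 5.49) in M1 and M2 EVs, and 0.347% (0.342 to 0.352) and 0.447% (0.442 to 0.452) in M1 and M2 cells. Ribosomal RNA had been removed before sequencing. Here and in the comparisons below, its level can therefore also depend on how completely it was removed from each library, which was not measured. Long noncoding RNAs took 5.37% (5.26 to 5.48) and 5.75% (5.65 to 5.86) of the EV reads, and 1.495% (1.485 to 1.505) and 1.23% (1.23 to 1.24) of the cell reads. The 10 features with most reads took 22.4% and 16.0% of the reads of M1 and M2 EVs and 9.15% and 11.2% of those of M1 and M2 cells. Although the EV libraries were the smaller, at least 1 read fell in 21884 and 22327 features of M1 and M2 EVs, and in 15884 and 16134 features of M1 and M2 cells. A count of at least 50 reads was reached by 48 and 54 features in the EVs and by 8907 and 8976 features in the cells.

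**Figure D1:**
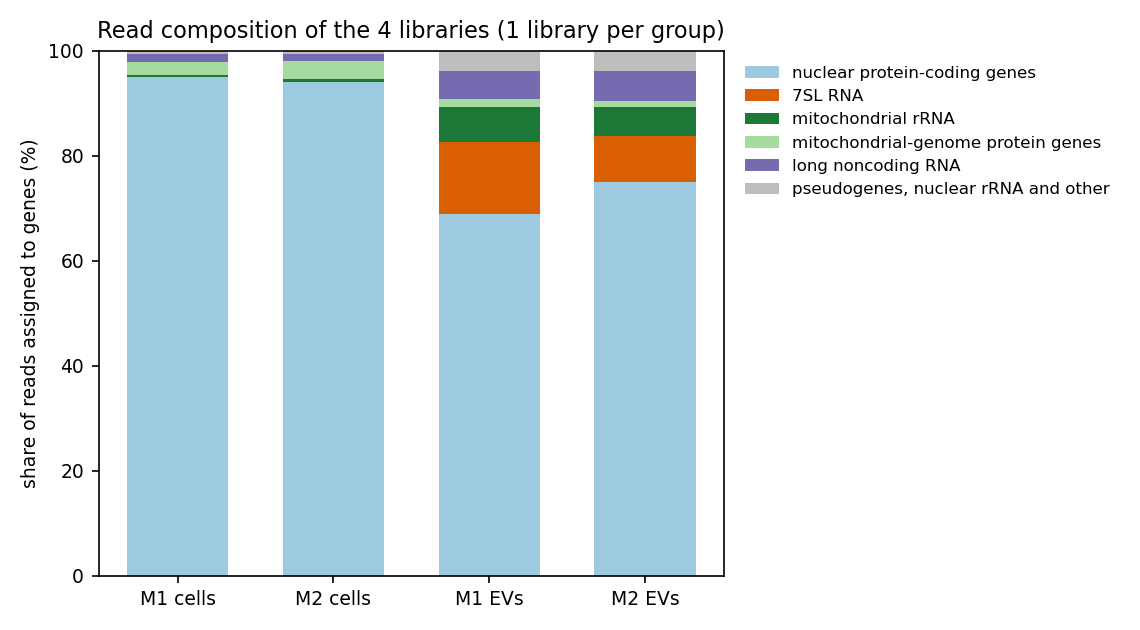
Percent of each library's reads by class of RNA, for 1 library per bar. 7SL RNA and mitochondrial ribosomal RNA make up 13.7% and 6.82% of the reads of M1 EVs and under 1% of the reads of either cell library.

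M1 cells were compared with M2 cells to ask how the 2 macrophage states differed after the co-culture. M1 cells held less messenger RNA for many chemokines, interferon-induced genes, matrix-degrading enzymes and M2 markers, and more for cholesterol synthesis. FABP4, a fatty acid carrier of macrophages and fat cells, was 472-fold lower in M1 cells, at 3 against 2199 reads (log2 ratio -8.88, -11.38 to -7.55). CXCL9, an interferon-gamma-induced chemokine that draws T cells, had 79 reads in M1 cells and 0 in M2 cells. With 3 reads as the limit for a count of 0, it was at least 35.1-fold higher in M1 cells. MSMO1, an enzyme of cholesterol synthesis, was 3.41-fold higher (log2 ratio 1.77, 1.61 to 1.94). FABP4 (Entrez Gene 2167) lies on chromosome 8 from 81478419 to 81483263, CXCL9 (4283) on chromosome 4 from 76001275 to 76007488 and MSMO1 (6307) on chromosome 4 from 165327623 to 165343160, all in build GRCh38.

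Of 28 M2 polarization markers, 13 were past the floor of 50 reads. Of these, 6 were at least 2-fold lower in M1 cells and 2 at least 2-fold higher, with a list median of -0.77. The lower ones included MS4A4A (5.42-fold), a membrane protein of alternatively activated macrophages, IL1RN (4.43-fold), the antagonist of the interleukin-1 receptor, and CD163 (3.85-fold), the scavenger receptor for hemoglobin. CCL22, a chemokine for regulatory and type 2 helper T cells, had 3 against 54 reads (log2 ratio -3.55, -6.08 to -2.13). The M1 polarization markers went both ways: of 13 past the floor, 3 were at least 2-fold higher and 1 at least 2-fold lower. INHBA, a subunit of activin, was 2.33-fold higher and IL15RA, the receptor chain that presents interleukin-15, was 2.09-fold higher (log2 ratio 1.06, 0.49 to 1.66), while CCL5, a chemokine for T cells and monocytes, was 3.88-fold lower. The M1 list's median was -0.03, its mean 0.57 and the log2 ratio of its summed reads -0.64, so the list had no single direction.

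Chemokines, interferon-stimulated genes and inflammatory cytokines were lower in M1 cells as lists. Of 16 chemokines past the floor, 9 were at least 2-fold lower and 2 at least 2-fold higher, with a median of -1.38. CCL8, which attracts monocytes, was 9.15-fold lower (log2 ratio -3.19, -3.44 to -2.96), and CXCL6 and CXCL8, which attract neutrophils, were 4.29-fold and 2.18-fold lower. CXCL8 was the most abundant feature of M2 cells, with 128818 reads against 44320 in M1 cells. Of 19 interferon-stimulated genes, 11 were at least 2-fold lower and 0 at least 2-fold higher, with a median of -1.30. IFIT1 (8.46-fold), OAS1 (5.48-fold) and OAS3 (4.44-fold), sensors of viral RNA, were among them, as was LY6E at 4 against 117 reads (log2 ratio -4.29, -6.36 to -3.06). The inflammatory and NF-kB list had a median of -0.49 with 2 of 21 members at least 2-fold lower, namely the growth factor CSF2 (5 against 106 reads, log2 ratio -3.86, -5.64 to -2.72) and the adhesion molecule ICAM1 (2.24-fold). BIRC3 and IL18 of this list had log2 ratios of -0.97 and -0.93. The guanylate-binding and interferon-gamma effector list, which holds CXCL9, had a median of 0.14, which turned to -0.03 and -0.07 under the 2 other scalings, and a log2 ratio of its summed reads of -0.65.

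Genes for scavenging, lipid handling and matrix remodelling were lower in M1 cells as lists, with some members higher. Of 14 scavenger and lipid handling genes, 4 were at least 2-fold lower and 2 at least 2-fold higher, with a median of -0.72. OLR1, a receptor for oxidized low-density lipoprotein, was 5.85-fold lower, while TREM2, a lipid-sensing receptor, and ABCA1, which exports cholesterol from cells, were 4.64-fold and 3.87-fold higher. Of 17 matrix genes, 6 were at least 2-fold lower and 1 at least 2-fold higher, with a median of -0.61. The metalloproteinases MMP12, MMP8 and MMP19 were 9.45-fold, 3.94-fold and 2.87-fold lower, whereas MMP14, which is bound to the membrane, was 4.03-fold higher. MMP1, the interstitial collagenase, was among the 5 features with most reads in both cell libraries and was 1.68-fold lower (log2 ratio -0.75, -0.76 to -0.73).

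Cholesterol synthesis genes were higher in M1 cells. Of 20 measured members, 18 had a higher share of the reads, 6 of them by at least 2-fold, and 0 were at least 2-fold lower, with a median of 0.90. DHCR7, which makes cholesterol in the last step of one branch of the pathway, was 3.12-fold higher, and HMGCS1 and CYP51A1, enzymes of its earlier steps, were 2.92-fold and 2.67-fold higher. Monocyte markers had a median of 0.76, with 8 of 8 measured members higher and 2 at least 2-fold higher: LYZ, the lysozyme gene, was 3.03-fold higher (log2 ratio 1.60, 1.56 to 1.63) and S100A8, a calcium-binding protein of young myeloid cells, 2.32-fold higher. S100A9 and S100A12 had log2 ratios of 0.82 and 0.94. The neutrophil and eosinophil list had a median of 0.82 over 5 measured members, and it shares S100A8, S100A9 and S100A12 with the monocyte list, while its member MMP8 was lower. Replication-dependent histones had a median of 0.74 with 2 of 6 members at least 2-fold higher, H2BC5 (2.72-fold) and H1-2 (2.44-fold). H2AC6 and H2BC21 had log2 ratios of 0.83 and 0.65. Proliferation genes had a median of 0.69 with 0 of 11 members at least 2-fold higher, and MCM5, MCM4, HMGB2 and CENPF had log2 ratios of 0.98, 0.82, 0.92 and 0.75.

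Several abundant gene classes were lower in M1 cells by less than 2-fold. Mitochondrial-genome protein genes had a median of -0.49 with 0 of 13 members higher, and MT-CO3, MT-ND4L, MT-ND3 and MT-ND4, subunits of the respiratory chain, had log2 ratios of -0.66, -0.63, -0.62 and -0.54. Cytosolic ribosomal proteins had a median of -0.20 with 11 of 66 members higher, and RPS10, RPS27A and RPL12 had log2 ratios of -0.93, -0.62 and -0.55. Translation factors had a median of -0.20, with log2 ratios of -0.48 for NPM1, -0.46 for EIF3E, -0.45 for EEF1A1 and -0.33 for EEF1B2. Small structural noncoding RNAs had a median of -0.65 over 5 members, among them RPPH1, the RNA of ribonuclease P, at 3.98-fold lower, and RN7SL1, RN7SK and RN7SL2 at log2 ratios of -0.77, -0.65 and -0.37. Metallothioneins and oxidative stress genes had a median of -0.25 but a log2 ratio of summed reads of 0.08. FTH1, the ferritin heavy chain and the most abundant feature of M1 cells, had a log2 ratio of 0.46. HMOX1, which degrades heme, was 2.13-fold lower, and OSGIN1, MT2A and GCLC had log2 ratios of -0.92, -0.75 and 0.74. Of the other abundant features, FTL, MT-CO1 and the glycolytic enzyme PKM had log2 ratios of -0.25, -0.44 and 0.12, the last of which turned to -0.05 and -0.08 under the 2 other scalings.

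Among protein-coding genes with at least 200 reads in either library, those with the highest ratios in M1 cells were RIPOR2, an inhibitor of RhoA (9.64-fold), the cadherin CDH24 (6.75-fold), the neural cell adhesion molecule NCAM1 (6.26-fold), MFGE8, which bridges phagocytes to dying cells (5.87-fold), the homeobox gene DLX1 (5.47-fold) and SLC44A2, a choline transporter-like protein (5.28-fold). Markers of other cell types took small shares of the cell libraries. MSC markers took 0.0418% of the reads of M1 cells and 0.0249% of those of M2 cells, and T and NK cell markers 0.0219% and 0.0330%. Erythrocyte markers had 203 reads in M1 cells and 25 in M2 cells, B and plasma cell markers 16 and 11 reads, platelet markers 344 and 975 reads, and liver and serum protein genes 142 and 232 reads. Endothelial and epithelial markers, which include PECAM1 and other genes that macrophages also express, took 0.117% and 0.0493%.

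**Figure D2:**
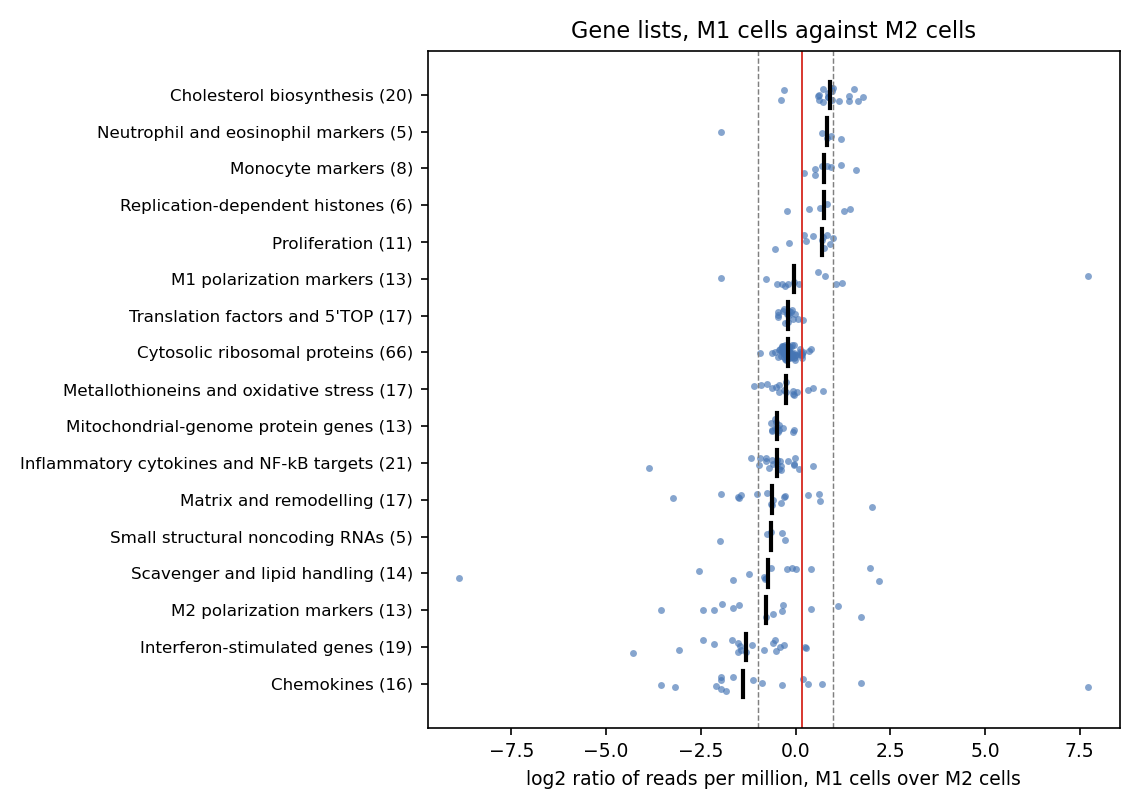
Log2 ratio of M1 cells over M2 cells for each gene past the floor (points) in the lists that stood apart from random lists and in the M1 polarization list, with 1 library per group; black bars mark list medians, dashed lines 2-fold, and the red line the median of all genes at 0.17. Chemokines sit around a median of -1.38 and cholesterol synthesis genes around 0.90, and the point for CXCL9 at 7.73 has 0 reads in M2 cells, so its height depends on the 0.5 read added to each library.

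In all, 9257 genes were past the floor in the cell comparison. Of these, 486 were at least 2-fold higher in M1 cells and 133 at least 2-fold lower, and for 166 and 84 of these the counting interval lay wholly beyond 2-fold. The 2-fold rule recovered 97.0% of simulated 2.5-fold differences at this depth, and counting error alone put 1.7 genes past it. Of 38 lists, 16 stood apart from random lists of matched expression, 5 higher and 11 lower in M1 cells. Without a floor, histones (0.41), proliferation (0.18) and neutrophil and eosinophil genes (0.77) no longer did, and the M1 polarization list (-0.21) did so as lower. The median of all genes was 0.17 and moved to -0.00 with median-of-ratios and -0.04 with TMM scaling, which took the higher and lower counts to 299 and 187, and to 276 and 202. The share that was higher went from 78.5% to 61.5% and 57.7%. Lists that did not stand apart included MHC class II, with a median of 0.39 but a log2 ratio of summed reads of -0.20.

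M1 EVs were compared with M2 EVs to ask whether the vesicles of the 2 states carried different RNA. At this depth the vesicles could be compared for 60 features, of which 36 were nuclear protein-coding genes, and 59 of the 60 differed by less than 2-fold. RN7SL2 and RN7SL1, the genes of 7SL RNA, were 1.55-fold higher (log2 ratio 0.63, 0.59 to 0.67) and 1.52-fold higher in M1 EVs. The mitochondrial ribosomal RNAs MT-RNR2 and MT-RNR1 were 1.26-fold and 1.29-fold higher. FTL and FTH1, the light and heavy chains of the iron store ferritin, went opposite ways, with log2 ratios of 0.61 (0.33 to 0.89) and -0.40 (-0.67 to -0.13). HBB, the beta chain of hemoglobin, which was chosen after its values were seen, was the 1 gene past 2-fold, with 76 against 23 reads (log2 ratio 1.78, 1.12 to 2.55).

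The 10 mitochondrial-genome protein genes past the floor had a median of 0.31 in M1 EVs over M2 EVs, or 0.12 under median-of-ratios scaling, with log2 ratios of 0.45 for MT-ND5, 0.40 for MT-CO1, 0.31 for MT-ND4 and 0.28 for MT-CYB. In M1 cells the same list had been lower, at -0.49. The small structural RNAs had a median of 0.19 over 8 members, with a turn to -0.00 under median-of-ratios scaling, and the ribonuclease P RNA RPPH1 had a log2 ratio of 0.11, which turned to -0.08 under that scaling. TTN, the giant muscle protein titin, had 200 and 212 reads in M1 and M2 EVs, a log2 ratio of -0.00. No M1 or M2 polarization marker reached 50 reads in either EV library, and the summed reads of these lists were 129 against 156 for M1 markers (log2 ratio -0.19, -0.54 to 0.15) and 175 against 143 for M2 markers (0.37, 0.04 to 0.70). Summed reads of the chemokines were 84 and 88 and those of the interferon-stimulated genes 161 and 209, with log2 ratios of 0.01 (-0.44 to 0.46) and -0.30 (-0.60 to 0.01). The summed chemokine reads of the cells had a log2 ratio of -1.14, which lies below the lower bound of -0.44 in the EVs. EV reads also fell widely on genes without cell reads, as described below. Such reads draw these EV sums toward equal levels whatever the cells held. The values therefore do not show whether the cell difference was carried into the vesicles. MSC markers took 0.131% and 0.149% of the reads of M1 and M2 EVs.

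Of the 60 features, 1 was at least 2-fold higher and 0 at least 2-fold lower in M1 EVs. No list stood apart. Only the mitochondrial-genome protein genes (10 members past the floor) and the small structural RNAs (8) had enough members to do so. For all other lists the outcome was fixed by the depth, so it does not show whether the vesicles were alike in them. The median of all features was 0.07, -0.11 under median-of-ratios and 0.21 under TMM scaling. Across the 44 genes past the floor in both the cell and the EV comparison, the M1 over M2 ratios of cells and EVs had a Pearson r of 0.17 and a Spearman rho of -0.28, with genes not being independent replicates. Signs were the same in 27.3% of these genes. HBB, at log2 ratios of 3.47 in cells and 1.78 in EVs, was the 1 gene at least 2-fold higher in both. Pearson's r was -0.71 with the floor raised to 200 reads, which left only 11 genes and not HBB.

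M1 EVs were compared with M1 cells, and M2 EVs with M2 cells, to ask which RNAs of the macrophages were relatively rich or poor in what they released. In both, the members of a list counted as lower or higher were at least 2-fold so. In M1, the vesicles were rich in short structural RNAs and mitochondrial ribosomal RNA and poor in the cells' abundant messenger RNAs for chemokines, macrophage identity, ferritin and matrix enzymes. RN7SL1 was 433-fold higher in M1 EVs than in M1 cells (log2 ratio 8.76, 8.66 to 8.86) and RN7SL2 353-fold higher. RPPH1 was 1614-fold higher (log2 ratio 10.66, 10.18 to 11.23), and MT-RNR1 and MT-RNR2 were 41.1-fold and 15.9-fold higher. The last 2 values can also depend on how completely ribosomal RNA was removed from each library. LYZ, with 5 reads against 19704, was 108-fold lower (log2 ratio -6.76, -8.52 to -5.67), and CCL1, a chemokine for type 2 helper T cells, had 0 against 5641 reads, at least 56.8-fold lower. RN7SL1 (Entrez Gene 6029) lies on chromosome 14 from 49586580 to 49586878, RN7SL2 (378706) on chromosome 14 from 49862550 to 49862849 and RPPH1 (85495) on chromosome 14 from 20343075 to 20343407, in build GRCh38.

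All 8 small structural RNAs past the floor were higher in M1 EVs, with a median of 8.99. The U4 spliceosomal RNAs RNU4-2 and RNU4-1 had 145 and 85 reads in the EVs and 1 read each in the cells (log2 ratios 11.65, 9.73 to 17.54, and 10.88, 8.94 to 16.78), and SNORD3A, the U3 RNA of ribosomal RNA processing, was 598-fold higher. Proliferation genes were also higher, with 6 of 11 at least 2-fold higher and a median of 1.19, or 0.18 under TMM scaling. The replication helicase subunits MCM5, MCM6 and MCM3 were 5.99-fold, 5.08-fold and 3.23-fold higher and CENPF, a kinetochore protein, 4.10-fold higher on 6 EV reads (log2 ratio 2.04, 0.42 to 3.15, but -0.57 with an even background subtracted). The mitochondrial-genome protein genes were lower, at a median of -0.99 with 6 of 13 at least 2-fold lower, but less so than genes of matched expression (percentile 99.8). MT-CO3, MT-CO1, MT-CO2 and MT-ATP6 were 3.28-fold, 2.90-fold, 2.43-fold and 2.41-fold lower. Mitochondrial genes had no exonic length here, so the background subtraction did not reach them. Reads from mitochondrial DNA cannot be told apart from RNA in these values.

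Of the immune lists, chemokines, MHC class I and II, complement and monocyte markers stood apart as lower in M1 EVs. Others did not, with medians of 0.21 for interferon-stimulated genes (-0.80 under TMM scaling), -0.75 for guanylate-binding, -1.61 for inflammatory, -1.08 for immune checkpoint and -1.43 for neutrophil and eosinophil genes. Of 14 chemokines, 11 were at least 2-fold lower, with a median of -2.39, or -2.29 with members at 0 reads set to the 3-read limit. CXCL8, CCL2 and CCL20 had 28, 17 and 1 reads against 44320, 6982 and 1024 (log2 ratios -5.55, -3.59, and -4.37 with an interval of -10.26 to -2.47). MHC class II presentation genes had a median of -3.47 with 4 of 5 lower, among them CTSH, IFI30 and CTSS, enzymes that process antigens (21.6-fold, 15.9-fold and 11.1-fold). CD74, the invariant chain, had 2 against 204 reads (log2 ratio -1.30, -4.68 to 0.25, or 0.15 with a prior of 5 reads). MHC class I genes had 8 of 10 members at least 2-fold lower and a median of -2.76, or -2.15 with the member at 0 reads at its limit. B2M, the light chain of the class I complex, was 43.4-fold and the chaperone CALR 12.6-fold lower. Complement genes were lower in 6 of 6 (median -3.12), including the receptor C5AR1 with 2 against 4352 reads (log2 ratio -5.72, -9.08 to -4.18), C3 (11.5-fold lower) and CD46 (6.55-fold lower), and C3AR1 with 2 against 1236 reads (log2 ratio -3.90, -7.27 to -2.37). Monocyte markers had a median of -2.75, with S100A9 19.6-fold, S100A8 12.4-fold and the lipopolysaccharide co-receptor CD14 9.50-fold lower.

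Genes of macrophage identity, matrix and metabolism were lower too. Macrophage identity genes had 20 of 22 members at least 2-fold lower and a median of -2.86. The glycoprotein GPNMB was 49.2-fold lower, and PSAP and CTSB, lysosomal proteins, 33.2-fold and 28.0-fold lower. Matrix genes had 12 of 16 lower (median -2.55), with MMP1, MMP9, PLAUR and SPP1 lower by 50.6-fold, 24.4-fold, 24.3-fold and 21.7-fold. Metallothioneins and oxidative stress genes had 11 of 17 lower (median -2.55), with FTH1 20.3-fold, the cystine transporter SLC7A11 15.8-fold and the autophagy receptor SQSTM1 10.8-fold lower, and TXN at 2 against 1629 reads (log2 ratio -4.30, -7.67 to -2.77). Glycolysis genes had 14 of 18 lower (median -2.43), with PKM 17.2-fold, SLC16A3 16.1-fold, PGK1 13.3-fold and GPI 11.4-fold lower. Nuclear OXPHOS subunits had 29 of 34 lower (median -1.99), for example ATP5F1B at 12.9-fold and ATP5F1A at 9.82-fold, and COX4I1 and COX7C had 2 and 1 reads against 1109 and 661 (log2 ratios -3.74, -7.11 to -2.21, and -3.74, -9.63 to -1.84). Cytosolic ribosomal proteins had 63 of 65 lower (median -2.18). Yet they held 1.28 (1.18 to 1.39) times the reads of a mixture of cell RNA with evenly spread reads. That mixture was fitted after the results were seen. Glycolysis, nuclear OXPHOS and cholesterol synthesis genes held 0.92 (0.82 to 1.03), 1.00 (0.84 to 1.19) and 0.90 (0.76 to 1.06) times its reads. These intervals included equal reads. Macrophage identity, matrix, oxidative stress and vesicle protein genes held 0.51, 0.49, 0.73 and 0.83 times its reads, with intervals below equal. Without their 3 members of most expected reads, the same lists stood at 0.72, 0.75, 0.75 and 0.96. RPL5, RPS16, RPS7 and RPL37A had 1, 3, 3 and 3 EV reads and log2 ratios of -4.72 (-10.61 to -2.82), -3.86 (-6.36 to -2.53), -3.77 (-6.27 to -2.44) and -3.44 (-5.94 to -2.11). Cholesterol synthesis genes had 14 of 20 lower (median -1.50), with SQLE 11.5-fold and CYP51A1 7.70-fold lower, and MSMO1 and INSIG1 at 2 and 3 reads against 1095 and 1077 (log2 ratios -3.73, -7.10 to -2.19, and -3.22, -5.72 to -1.89). The messenger RNAs of proteins known from vesicles themselves had 18 of 25 lower (median -1.97), including CD82, CD63, LAMP1 and LAMP2 at 21.1-fold, 18.1-fold, 17.6-fold and 14.7-fold.

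Neither polarization list stood apart in M1 EVs against M1 cells: the M1 list had a median of -0.75 and the M2 list one of -0.13, which turned to 0.20 under median-of-ratios scaling. Of the M1 markers, IL1B (45.7-fold) and PTGS2 (16.4-fold), mediators of inflammation, were lower, INHBA had 2 against 2042 reads (log2 ratio -4.63, -7.99 to -3.09) and IL15RA was 4.23-fold higher. Of the M2 markers, VSIG4 had 2 against 2079 reads (log2 ratio -4.65, -8.02 to -3.12), IL1RN was 3.07-fold lower, and the scavenger receptor STAB1 and the matrix protein FN1 were 20.3-fold and 2.33-fold higher. Among coding genes with at least 200 reads in M1 EVs or M1 cells, the highest ratios were those of TTN (110-fold), ANKS1A (8.26-fold), DST (6.75-fold), DOCK9 (5.69-fold), UTRN (5.45-fold) and MYO15B (4.85-fold), of which TTN has the longest exonic sequence, at 116859 bases. With an even background subtracted, the log2 ratio of TTN went from 6.78 to 6.15 and that of DST from 2.75 to 2.19, while ANKS1A went from 3.05 to 3.93. Such a subtraction cannot remove reads concentrated at single places of the genome, so these ratios do not show that transcripts were enriched. The lowest among the same genes, beside CCL1 and LYZ, were those of EPHX1 and CES1, enzymes of drug metabolism with 0 EV reads (at least 15.8-fold and 14.7-fold lower), IL2RG with 1 against 4192 reads (log2 ratio -6.40, -12.29 to -4.51) and the integrin ITGB2 (54.3-fold lower). FTL was 9.02-fold lower.

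Of 8916 genes past the floor, 1687 were at least 2-fold higher and 2990 at least 2-fold lower in M1 EVs, and the counting interval lay wholly beyond 2-fold for 388 and 1154. The median of 7 EV reads per gene limits this comparison. In simulated libraries without any difference counting error alone put 915 genes past 2-fold and 0.65 genes past it with their whole interval. The 2-fold rule recovered 68.9% of simulated 2.5-fold differences. Against random lists of matched expression, 13 lists stood apart as lower and 3 as higher. Without a floor, complement and monocyte markers turned to medians of 3.56 and 0.78, and MHC class II (-1.30), mitochondrial-genome (-0.99) and proliferation (2.59) genes no longer stood apart. With the EV background subtracted, MHC class I (-2.26), metallothionein and oxidative stress (-2.08) and monocyte (-2.27) genes no longer did, nor did vesicle protein (-1.28) and matrix (-1.45) genes with a prior of 5 reads. The median of all genes was -0.35, -0.01 under median-of-ratios and -1.36 under TMM scaling, with 2289 higher and 2346 lower genes and with 475 and 5294 genes. The share that was higher went from 36.1% to 49.4% and 8.23%.

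In M2, the vesicles were again rich in small structural RNAs and poor in abundant macrophage messenger RNAs. RN7SL2 and RN7SL1 were 176-fold and 167-fold higher in M2 EVs than in M2 cells (log2 ratios 7.46, 7.39 to 7.53, and 7.39, 7.31 to 7.46), and MT-RNR1 and MT-RNR2 34.5-fold and 9.34-fold higher. All 8 small structural RNAs were higher, with a median of 7.67, among them RPPH1 (376-fold), RNU4-2 (680-fold), SNORD3A (236-fold) and RNU4-1 at 77 against 1 read (log2 ratio 11.07, 9.13 to 16.97). CXCL8, the most abundant feature of M2 cells, was 112-fold lower in their vesicles (log2 ratio -6.81, -7.44 to -6.30), CCL2, the main monocyte chemokine, 155-fold lower, SPP1, which encodes osteopontin, 120-fold lower and MMP1 115-fold lower. CCL7, another monocyte chemokine, had 1 against 8264 reads (log2 ratio -7.04, -12.93 to -5.15), and RAP1B, a small GTPase of adhesion, and CCL8 had 0 EV reads (at least 15.7-fold and 15.4-fold lower).

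Both polarization lists were lower in M2 EVs than in M2 cells. Of 13 M2 markers, 8 were at least 2-fold lower and 3 at least 2-fold higher, with a median of -1.76. IL1RN was 40.9-fold lower, VSIG4 and CTSC had 1 and 3 EV reads (log2 ratios -4.35, -10.23 to -2.45, and -3.11, -5.61 to -1.78), and STAB1 was 19.0-fold higher. Of 11 M1 markers, 6 were at least 2-fold lower and 1 higher, with a median of -1.90, or -0.87 with the member at 0 reads at its limit. IL1B, PTGS2 and SLAMF7 were 57.7-fold, 9.54-fold and 4.87-fold lower, and CCL5 had 0 EV reads against 90 in the cells, a difference that was not detectable at this depth. That list's median was 0.11 with a prior of 5 reads. Scavenger and lipid handling genes were lower in 8 of 12 (median -2.66), with OLR1 at 0 EV reads (at least 9.36-fold lower) and FABP4 and NPC2 at 1 and 2 reads against 2199 and 2434 (log2 ratios -5.13, -11.02 to -3.24, and -4.54, -7.91 to -3.01). Immune checkpoint genes had 7 of 10 members at least 2-fold lower and 2 higher (median -1.54), with TGFB1 14.5-fold, SIRPA 9.90-fold and VSIR 6.02-fold lower and ENTPD1, an enzyme that degrades extracellular ATP, 9.39-fold higher. The neutrophil and eosinophil list had a median of -2.87 over 5 members, with S100A9 14.5-fold lower, MMP8 and S100A8 at 3 EV reads each (log2 ratios -3.85, -6.35 to -2.52, and -2.87, -5.37 to -1.54) and CSF3R, the receptor of a granulocyte growth factor, 3.74-fold higher (log2 ratio 1.90, 0.31 to 2.99).

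The lists for chemokines (12 of 15 lower, median -2.70), macrophage identity (19 of 22, -2.91), complement (5 of 6, -2.68), matrix (14 of 17, -2.56), metallothioneins and oxidative stress (12 of 17, -2.52), nuclear OXPHOS (27 of 33, -2.17), cytosolic ribosomal proteins (65 of 66, -2.43) and vesicle proteins (20 of 26, -2.35) were lower in M2 EVs, as in M1 EVs. Among them, the lysosomal protease CTSD was 72.6-fold, GPNMB 72.0-fold, LYZ 37.8-fold and PSAP 32.3-fold lower. C5AR1, C3 and CD55 were 30.4-fold, 12.6-fold and 3.26-fold lower, and PLAUR and TIMP1 33.7-fold and 23.5-fold lower. Lower values also held for SQSTM1 18.2-fold and FTL 16.4-fold, ATP5F1B 11.6-fold and UQCRC1 8.43-fold, and for RPL19 14.6-fold, RPS27 13.97-fold and RPS3A 10.1-fold. LAMP2, ANXA5, CD63 and LAMP1 were 31.3-fold, 17.7-fold, 14.6-fold and 13.6-fold lower. MT2A had 0 EV reads (at least 12.8-fold lower), and C3AR1, NQO1, COX7C, NDUFS5 and RPL39 had 2, 2, 1, 2 and 2 EV reads with log2 ratios of -4.60 (-7.97 to -3.07), -4.63 (-8.002 to -3.10), -3.70 (-9.59 to -1.80), -3.34 (-6.71 to -1.81) and -4.15 (-7.51 to -2.61). MHC class II genes had a median of -3.27 with 3 of 5 members lower and 2 higher. IFI30, CTSS and CTSH were 31.9-fold, 19.5-fold and 9.63-fold lower, and CD74 was 3.92-fold higher on 5 EV reads (log2 ratio 1.97, 0.17 to 3.15). Translation factors were lower in 15 of 17 (median -2.47), with NPM1 19.0-fold, TPT1 10.9-fold, EEF1A1 10.04-fold and RACK1 8.59-fold lower. Heat shock genes were lower in 14 of 19 (median -2.003), with the chaperones HSPA5 and HSP90AA1 17.2-fold and 8.72-fold lower, the stress regulator ATF4 6.77-fold lower and HSPH1 at 3 EV reads (log2 ratio -2.98, -5.48 to -1.65). Hosts of small nucleolar RNAs had 5 of 11 members lower and 3 higher, with a median of -0.99, or -0.78 with members at 0 reads at their limit. SNHG6 had 0 EV reads (at least 1.71-fold lower). SNHG1 had 0 EV reads against 139 in the cells, but its counting interval included equal levels. SNHG5 and SNHG7 had 2 and 1 reads (log2 ratios -1.66, -5.03 to -0.11, and -1.42, -7.31 to 0.50). With a prior of 5 reads SNHG1 and SNHG7 turned to 0.54 each.

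Among coding genes with at least 200 reads in M2 EVs or M2 cells, the highest ratios were those of TTN (86.5-fold), FKBP5, a glucocorticoid-induced co-chaperone (10.3-fold), ANKS1A (8.03-fold), the anchoring collagen COL7A1 (7.44-fold), DOCK3 (6.19-fold) and PDK1, a kinase that restrains pyruvate oxidation (5.97-fold), with 167 reads in the EVs and 1171 in the cells. With an even background subtracted, TTN went from a log2 ratio of 6.44 to 5.57 and PDK1 from 2.58 to 3.84. These ratios, too, can hold reads concentrated at single places of the genome, which was not tested. FTH1 and MT-CO1 were 11.2-fold and 5.17-fold lower. Of 8989 genes past the floor, 2440 were at least 2-fold higher and 2587 at least 2-fold lower, and the interval lay wholly beyond 2-fold for 771 and 1106. Counting error alone put 1098 genes past 2-fold in simulated libraries, and 67.9% of simulated 2.5-fold differences were recovered. In this comparison 17 lists stood apart as lower and 1 as higher. MHC class I (-1.44), glycolysis (-1.98), monocyte (-2.30), cholesterol synthesis (-0.45), mitochondrial-genome (-1.84) and proliferation genes (1.43, or -0.09 under TMM scaling) stood apart in M1 EVs but not in M2 EVs. Scavenger (-0.62 in M1), translation (-2.07), heat shock (-1.68) and snoRNA host genes (-0.76) did so in M2 EVs but not in M1 EVs. Whether the 2 types differed in these lists was not tested. Without a floor, 7 of the lower lists turned to positive medians, namely both polarization lists (3.06 and 2.73), MHC class II (1.88), complement (3.04), scavenger (2.69), immune checkpoint (2.21) and neutrophil and eosinophil genes (6.12). With a prior of 5 reads translation (-1.81) and matrix (-1.55) genes no longer stood apart, nor did hosts of small nucleolar RNAs (-0.47) with the EV background subtracted. The median of all genes was -0.04, 0.40 under median-of-ratios and -1.56 under TMM scaling, with 3264 higher and 1885 lower genes and with 473 and 5648 genes. The share that was higher went from 48.5% to 63.4% and 7.73%.

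**Figure D3:**
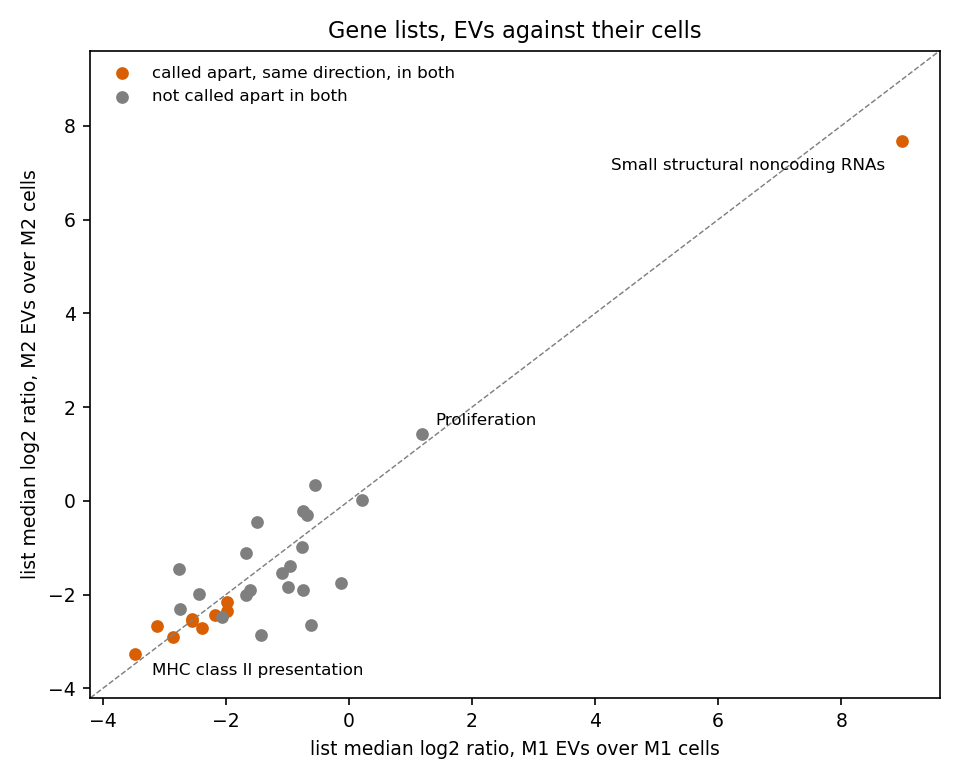
List medians of the log2 ratio of EVs over cells, for M1 on the horizontal and M2 on the vertical axis, with 1 point per gene list and 1 library per group; the dashed line marks equal values. Of 31 lists measured in both, 10 (orange) stood apart in the same direction in both, 9 lower and 1 higher, the small structural RNAs at 8.99 and 7.67.

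Across the 8632 genes past the floor in both, the EV over cell ratios of M1 and M2 had a Pearson r of 0.81 and a Spearman rho of 0.80, with genes not being independent replicates. EV reads per gene were few, and the cell level of each gene divides its ratio. So r includes what similar cell levels in M1 and M2, evenly spread EV reads and the shared floor and prior bring. It was 0.94 without a floor and 0.64 with the EV background subtracted. Of the genes at least 2-fold higher in M1 EVs and in M2 EVs (1491 and 2178 of these 8632), 1203 were higher in both, where independent sets would share 376. Of the 2976 and 2567 lower ones, 2030 were lower in both, where independent sets would share 885. For the same reasons, independent sets are a weak baseline here.

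The EV reads were also widespread among genes that the cells did not transcribe measurably. Of the protein-coding genes, 4552 had 0 reads in both cell libraries, and 74.8% of these had at least 1 read in M1 EVs and 77.2% in M2 EVs. Their density was 1.20 reads per kilobase of exon in M1 EVs and 1.41 in M2 EVs. Spread evenly over the exons of all nuclear protein-coding genes, that density would give 71.6% and 73.6% of the EV reads of these genes. Across all coding genes, EV reads went with exonic length at a Spearman rho of 0.56 in M1 EVs and 0.55 in M2 EVs, and cell reads at 0.25 and 0.24. Every EV value above is a share of all EV reads, these included. The random lists were matched on expression and not on exonic length. A low percentile of EVs over cells therefore does not by itself show that a list was depleted.

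**Figure D4:**
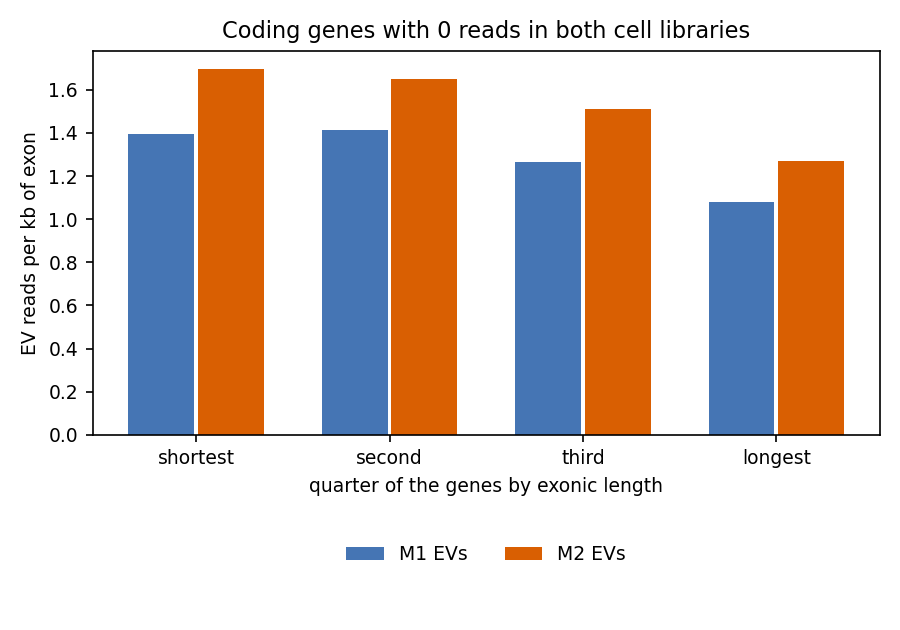
EV reads per kilobase of exon in the 4552 protein-coding genes with 0 reads in both cell libraries, in 4 bins of exonic length, for 1 M1 EV and 1 M2 EV library. Density lies between 1.08 and 1.41 in M1 EVs and between 1.27 and 1.70 in M2 EVs.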

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

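Tests of exchanged labels, of a mixture, of other background densities and of counting error, and the use of RefSeq-paired exon lengths, were chosen only after the results they concern had been seen. The other tests of this part were set out beforehand. Reads in genes without cell reads, nearly all of which lie below the floor of the report's comparisons, drew attention: 8.975% of the reads of M1 EVs (Clopper-Pearson 95% interval 8.84 to 9.11) and 10.03% of those of M2 EVs (9.89 to 10.2) fell in the 4552 protein-coding genes with 0 reads in both cell libraries, above the limit that a count of 0 allows.

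Reads from another cell type or from serum are argued against as the whole source, since the 100 such genes with most reads per kilobase held 4.52% of these reads (3.98% with all annotated exons), where a set of expressed genes would have concentrated them. Reads spread evenly over the genome, as from genomic DNA, are consistent with a Spearman rho of 0.575 between EV reads and exonic length (0.54 with all annotated exons), and with olfactory receptor genes, which macrophages are not known to transcribe, holding 0.688 times as many reads per kilobase as the other genes of this set (0.638 to 0.741). That ratio argues against specific packaging of transcripts for the olfactory receptor genes. For the wider set packaging cannot be told apart from shared ease of mapping, because M1 and M2 EV reads went together at a partial rho of 0.64 given length (0.66 with all annotated exons) and both would give this.

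The cells' most abundant transcripts were scarce in the vesicles: of the 413 genes with at least 2000 reads in M1 cells and the 650 in M2 cells, 390 and 586 had an interval wholly beyond 2-fold lower, and the lower of these shares, 90.2%, argues against counting error at the EV depth. For shares of the whole library, dilution by evenly spread reads is argued against as the whole cause. After subtraction 381 of 401 and 565 of 623 genes stayed at least 2-fold lower. The highest median of the 2 types was -2.23, past the bound of -1 set beforehand. It was -1.73 at the most reads subtracted (1.3 times the silent density). The library totals also hold small structural RNA and mitochondrial ribosomal RNA, which the subtraction leaves in place. Their large share of the EV reads lowers every coding share, so these medians do not decide dilution within the coding reads. Thinning the cell libraries to EV depth (-2.83) changes all genes alike and decides nothing. Within the nuclear coding reads alone, the subtracted medians were -1.25 in M1 and -1.33 in M2. They rose to -0.92 and -0.94 at 1.1 times the silent density and to 0.54 and 0.95 at 1.3 times. That leaves dilution open there, and a mixture of whole-cell RNA with evenly spread reads cannot be told apart. Summed reads were at most 0.346 (chemokines), 0.490 (matrix), 0.492 (MHC class II) and 0.554 (macrophage identity) times the expected in both types. These sums rest largely on few genes. Without the 3 of most expected reads they were at most 0.606, 0.755, 0.715 and 0.855, though MHC class II stayed at 0.438 in M1. Cytosolic ribosomal proteins (68 genes) departed upward, at 1.28 times the expected in both types with lower bounds of 1.18. Without their 3 largest they stood at 1.31 and 1.33. For nuclear OXPHOS subunits the intervals included equal reads (0.84 to 1.19 and 0.93 to 1.28). Of all nuclear coding genes with at least 2000 cell reads, the best mixture with up to 2 times the silent density left 11.96% outside its counting range in M1 and 7.85% in M2 (15.3% and 11.7% with up to 1.45 times, 9.67% and 4.97% with up to 3 times), where 10% or less would go with the mixture and 25% or more against it. Selective release of some RNAs by the macrophages is the biological explanation the design allows, and it was not tested.

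Lists for M2 markers, interferon-stimulated genes and chemokines were lower in the library labelled M1 cells. Counting error is argued against, as 62.5% of the chemokines (10 of 16) had an interval wholly below equal levels. An exchange of the cell labels cannot be told apart: the M2 list's median of -0.77 and the higher CXCL9 go with the labels, whereas lower interferon-stimulated genes and chemokines would more readily go with the labels exchanged, and no second library of either group was analysed here. Thinning M2 cells to the depth of M1 cells left the chemokine median at -1.38, which decides nothing because it lowers all genes alike. A difference between the 2 macrophage states, between cell donors or in the response to MSCs may also underlie the pattern, none of which was tested.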

How the results depend on the processing

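The deposited log2 CPM, the EV background subtraction and the restriction to intervals wholly beyond 2-fold were chosen after seeing the data; the other 6 alternatives were planned. Each group has 1 library, so no replicate could be left out. A fit that pairs EVs with cells over M1 and M2, with the 2 types standing in for replicates, was not run. Ratios of named genes were the same within their intervals in 1301 of 1536 planned values, moved in 231 and reversed in 4; list medians kept direction and side of the threshold in 499 of 540, lost it in 14, gained it in 15 and reversed in 12. Under the added alternatives 305 of 438 gene ratios and 129 of 159 list medians were the same. All scalings shift every gene of a comparison alike, so correlations have no value under them, lists of noncoding or mitochondrial genes have none under nuclear protein-coding genes alone, and cells have none under the EV background. EV depth limits the values of genes with few EV reads, since 1 read is over 5 CPM.

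M1 with M2 cells (619 genes apart, 486 higher, 133 lower): median-of-ratios gave 299 higher; TMM 276 higher and 202 lower; a floor of 200 reads 241 apart, 164 higher and 77 lower, with fewer genes by construction; no floor 4924, 3030 and 1894, with more; deposited log2 CPM 300 higher and 201 lower; intervals beyond 2-fold 250, 166 and 84, fewer by construction. M1 polarization markers, which did not stand apart, did so as lower in M1 cells with a floor of 200 reads (-0.29), no floor (-0.21) and deposited log2 CPM (-0.32), and proliferation genes no longer stood apart with no floor (0.18) and deposited log2 CPM (0.15). M1 with M2 EVs (1 apart, 1 higher, 0 lower, 0 lists): TMM gave 3 apart and 3 higher; the 200-read floor 0 and 0; no floor 7535, 3001 and 4534, with 2 lists; nuclear protein-coding genes 2 and 2; deposited log2 CPM 6820, 3282 and 3538, with 3 lists; the EV background subtraction 2 apart and 1 lower. M1 EVs with M1 cells (4677, 1687 and 2990): TMM gave 475 higher and 5294 lower; the 200-read floor 2852 apart and 127 higher; no floor 18267 and 15247; a prior of 5 reads 3268 higher and 1437 lower; deposited log2 CPM 17409 and 14773; intervals beyond 2-fold 1542, 388 and 1154. M2 EVs with M2 cells (5027, 2440 and 2587): TMM gave 473 higher and 5648 lower; the 200-read floor 2830 apart and 371 higher; no floor 18972 and 16369; the prior of 5 reads 3926 higher and 1371 lower; deposited log2 CPM 18169 and 15310; intervals beyond 2-fold 1877, 771 and 1106. The correlation of M1 over M2 ratios between cells and EVs went from 0.17 to -0.71 with the 200-read floor, which left only 11 genes and not HBB. That of EV over cell ratios between M1 and M2 went from 0.81 to 0.75 with the 200-read floor and 0.94 with no floor. It was 0.91 with the prior of 5 reads, 0.93 with deposited log2 CPM and 0.64 with the EV background subtracted. For M1 with M2 EVs, only the mitochondrial-genome protein genes and the small structural RNAs had enough members past the main floor to stand apart. Except where construction is named, the cause was not tested.

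Reversed medians of EVs over cells arose without a floor and with deposited log2 CPM, respectively, both of which admit genes with under 50 reads. In M1 these were complement (3.56 and 2.82), monocyte markers (0.78 and 0.90) and, without a floor, histones (3.46). In M2 they were M1 polarization (3.06 and 2.53), M2 polarization (2.73 and 2.36), MHC class II (1.88 and 1.66), complement (3.04 and 3.09), scavenger (2.69 and 2.31), immune checkpoint (2.21 and 1.19) and neutrophil and eosinophil lists (6.12 and 3.04). With the prior of 5 reads, which raises EV shares of genes with few EV reads by construction, reversed values were 0.36 for snoRNA host genes and 0.15 for CD74 in M1, and 0.11 for M1 polarization, 1.14 for CCL5, 0.54 for SNHG1 and 0.54 for SNHG7 in M2. With the EV background subtracted CENPF reversed to -0.57 in M1; the cause was not tested.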

Other observations

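The comparison of EV lists with a fitted mixture, reported in this part, was chosen only after the results had been seen. Several macrophage programmes differed little between M1 and M2 cells as lists, although single members did not always follow. Macrophage identity genes had a median log2 ratio of -0.09 (22 measured), complement genes 0.13 (6), MHC class I genes 0.18 (10), immune checkpoint genes -0.05 (10), glycolysis genes 0.09 (18), nuclear OXPHOS subunits 0.02 (34), hypoxia response genes 0.21 (11), heat shock genes -0.08 (19), immediate early genes 0.12 (17), vesicle protein genes -0.08 (26), nuclear-retained long noncoding RNAs 0.27 (9) and hosts of small nucleolar RNAs 0.16 (11), against 0.17 for all genes. Summed reads went otherwise for nuclear-retained long noncoding RNAs (log2 ratio 0.61, 0.59 to 0.64), immediate early genes (-0.22) and nuclear OXPHOS subunits (-0.04). Of these, 7 changed sign under the other scalings: complement, MHC class I, glycolysis, nuclear OXPHOS, hypoxia, immediate early and snoRNA host genes. Within MHC class I, 3 of 10 members were at least 2-fold higher in M1 cells and 0 lower, and within macrophage identity 3 were higher and 1 lower.

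Scaled to library totals, some gene groups were depleted little or not at all from the vesicles, but TMM scaling lowered each of the medians that follow. Evenly spread reads also raise the ratios of genes with few cell reads, so these medians do not by themselves show retention. Hypoxia response genes, among them PDK1, had medians of -0.68 in M1 and -0.30 in M2 for EVs over cells, which went to -1.69 and -1.82 under TMM scaling, and the second turned to 0.14 under median-of-ratios scaling. Their summed reads were 231 and 302 in the EVs, 2.06 (1.80 to 2.34) and 2.504 (2.23 to 2.80) times those of a fitted mixture of the cells' RNA with evenly spread reads. PDK1 alone held 132 and 167 of these reads, more than the 112 and 121 that the mixture gave the whole list. The excess therefore rested largely on PDK1 and does not describe the list. Interferon-stimulated genes had medians of 0.21 and 0.03, which turned to -0.80 and -1.49 under TMM scaling. Replication-dependent histones had medians of -0.55 and 0.34, which went to -1.56 and -1.18 under TMM scaling. Over their coding members the reads were 0.94 (0.64 to 1.33) and 1.20 (0.87 to 1.60) times the mixture's, which also included equal reads. Proliferation genes in M2 had a median of 1.43, which turned to -0.09 under TMM scaling, and 1.39 (1.20 to 1.59) times the mixture's reads. Erythrocyte markers held 112 and 55 reads in M1 and M2 EVs, 4.53 and 1.90 times the mixture's, and HBB alone held 76 and 23 of them. MSC markers held 228 and 273 reads, 1.18 and 1.22 times the mixture's over its coding members. B and plasma cell markers held 51 and 63 EV reads, T and NK cell markers 70 and 98, platelet markers 30 and 36, liver and serum protein genes 54 and 73, and endothelial and epithelial markers 83 and 84.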
